A study of Homo sapiens with 3 samples.

How the data were processed

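The series holds 3 libraries of eCLIP, a method in which RNA crosslinked to a protein by UV light is precipitated with the protein and sequenced. The cells were LS174T, a human colon adenocarcinoma line, transfected for 24 h with a mouse pregnane X receptor (Pxr, gene Nr1i2) carrying an HA tag. Per the labels' protocols, 20 M cells per reaction were irradiated at 254 nm with 400 mJ/cm2, and lysates were digested with RNase I and DNase at 37 °C before incubation with antibody. The protocol names antibodies against PXR, against HA and a control IgG, and which of them served for each library is not given in the sources used here. DNA of 175 to 300 bp was selected after 9 to 18 PCR cycles. By the labels, 1 library was an input and 2 were replicates of the PXR immunoprecipitate.

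The data analysed here are 1 list of peaks. The submitters' processing notes name cutadapt, BWA, MACS2 and the hg38 build, without versions or settings. Whether the list came from both immunoprecipitate replicates together or from 1 of them is not given in the sources used here. Peaks were called apart on the plus and minus strands, as their deposited names show. The deposited score of a peak equalled the integer part of 10 times its −log10 q in all 21031 peaks. The deposited fold is the caller's ratio of reads at the summit to a background, each with 1 added. The deposited −log10 p and −log10 q come from the caller's Poisson test, and the lowest −log10 q was 1.31. The last deposited column is the distance of the summit from the peak start, in bases. Fold, −log10 p and −log10 q are the authors' values throughout. They were used to describe, rank, filter and compare peaks within this list, and fold and −log10 p also to recover read counts and backgrounds. No values of single libraries were used here, so no result has a spread between replicates, and no test between immunoprecipitate and input was made.

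The number of reads under each summit was recovered from the fold and the −log10 p, as the whole number k and the background b for which the fold is (k + 1)/(b + 1) and the Poisson probability of more than k reads gives the deposited p. A whole number met the deposited −log10 p within 0.0001, plus a 0.00001 part of it, in 21028 of 21031 peaks. In 29 peaks a different whole number came within 0.001 as well. Multiplied by 50, the recovered background was a whole number within 0.05, or lay at 1 common level per strand, in 21004 peaks (99.9%). A whole number is what a count of reads in 10 kb gives when scaled to 200 bases. The common level was 0.286 reads per 200 bases on the plus strand and 0.236 on the minus strand, and 637 peaks lay at it. If the caller used its preset human genome size of 2700000000 bases, these levels correspond to 3.86 M plus-strand and 3.18 M minus-strand reads. The fold therefore compares a summit with the 10 kb around it, except in those 637 peaks, where it compares the summit with the common level. Against the 10 kb, a long, evenly covered RNA gives low folds and an isolated short one gives high folds. Intervals of read counts are exact Poisson intervals at 95%. They cover counting error only, since copies made in PCR are not independent molecules.

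Peak centres were assigned to genes by position in the NCBI RefSeq gene table of GRCh38.p14, which shares its coordinates with hg38 and holds 59792 genes. The table gives gene spans and classes. Exons, gene strand and sequence were not used here, so features were gene span and no gene, divided by gene class. Where classes overlapped, priority went to small noncoding RNA, then protein coding, lncRNA, pseudogene and other genes. The main set was chromosomes 1 to 22, X and Y. Shares were compared with 1000 random placements of the same number of positions per chromosome, between the chromosome start and the last gene or peak, by a two-sided permutation test whose smallest possible p is 0.002. Medians of fold were compared by two-sided permutation tests with 100000 resamples, with 1000 bootstrap draws for their intervals. Both families were adjusted by the Benjamini-Hochberg method. Peaks are not replicates, so these p-values describe this list.

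Before the data were examined, 24 gene lists were fixed, along with the tests of the report, a set of alternatives and the rule for naming genes. The tests on strand within genes, gene ends, the fold ceiling and NR1I2, and further alternatives, were chosen after seeing the data. The share of each list with a peak was set against 10000 random lists matched on gene length (20 bins) and on coding or noncoding class. A list was called above or below when it lay in the top or bottom 2.5% of random lists. Expression was not matched, because no expression values were used here. All list members were found in the gene table. The mitochondrial list was taken by chromosome, since the table writes those symbols without a prefix, and has no random lists.

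The rule named the 10 main-set peaks with the highest fold, the 10 genes with the most peaks, up to 4 members of each list with the highest fold, NR1I2 as the construct check, and the 5 noncoding genes with the highest fold, among which pseudogenes were not counted. Genes named outside the rule are marked as chosen after their values were seen. Alternatives covered the peak threshold, the contigs, merging of peaks within 100 bases, summit or overlap instead of centre (overlap against random intervals with the widths of the peaks), peaks in 1 gene only, random lists without length matching, and other measures than fold. Alternatives that need exons or sequence were not run.

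The scripts were tested on simulated data. The read count was recovered in 100% of 2000 simulated peaks. The gene share over random was 1.00 for uniform positions, and 1.38 where 1.38 had been put in. Of 200 simulated lists without an effect, 3.50% were called, and of 200 with raised odds 63.0% were called. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.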

Results

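The data describe where RNA fragments from an eCLIP of mouse PXR gathered in human LS174T colon cells. PXR is a nuclear receptor known as a sensor of drugs and bile acids, and the human gene for it is NR1I2. The groups were 1 input library and 2 immunoprecipitate replicates, represented here by 1 peak list. Values of single libraries were not analysed here, so no value below has a replicate error, and the fold is the authors' ratio of a summit to a background.

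Most peaks lay in protein-coding genes, and the deepest on chromosomes 1 to 22, X and Y lay in RPPH1 and RMRP, the RNAs of RNase P and RNase MRP. The list held 21031 peaks, 10995 on the plus strand and 10036 on the minus strand. Of these, 20919 lay on chromosomes 1 to 22, X and Y and covered 7.01 Mb. Their median width was 263 bases, with quartiles of 209 and 379 bases. The median fold was 5.98, with quartiles of 4.80 and 7.78, and 316 peaks had a fold of 20 or more. The median −log10 q was 9.14. The recovered depth at a summit had a median of 21 reads, for which the exact Poisson interval is 13.0 to 32.1. It was under 10 reads in 2143 peaks (10.2%) and over 200 reads in 225 peaks (1.08%). No fold in the list exceeded 50, and the background of every peak in the list held at least as many reads in 10 kb as its summit.

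**Figure D1:**
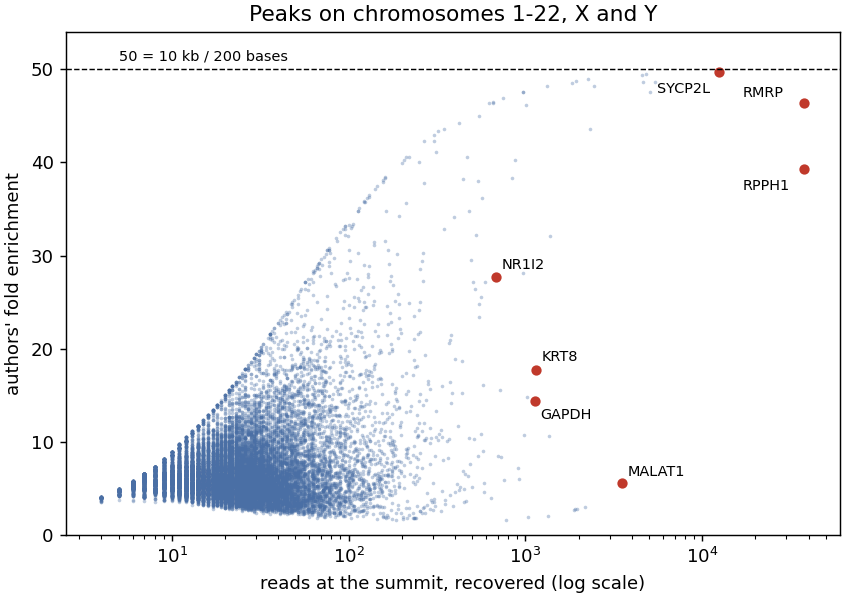
Each point is a peak on chromosomes 1 to 22, X and Y; the x axis is the recovered number of reads at the summit on a log scale, the y axis is the authors' fold enrichment, red points are the highest-fold peak of each named gene, and the dashed line is at 50. Folds stayed below the line at all depths, with SYCP2L at 49.8 from 12385 reads and MALAT1 at 5.55 from 3528 reads.

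The construct check concerned NR1I2, on chromosome 3 from 119782101 to 119818487 (hg38), whose mouse counterpart had been transfected. NR1I2 held 9 peaks, 5 on the plus strand and 4 on the minus strand. The highest, at 119807364 to 119807602 on the plus strand, had a fold of 27.7 and 682 reads (Poisson interval 632 to 735). Another plus-strand peak, at 119815357 to 119815611, had a fold of 24.8 and 546 reads (501 to 594). The deepest minus-strand peak, at 119811388 to 119811686, had a fold of 11.7 and 40 reads (28.6 to 54.5). Minus-strand summits held 5.73% of the summed summit reads of NR1I2. By its deepest summit NR1I2 ranked 13 among 8329 coding genes with a peak. The list does not separate reads of human NR1I2 RNA from reads of the mouse construct.

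**Figure D2:**
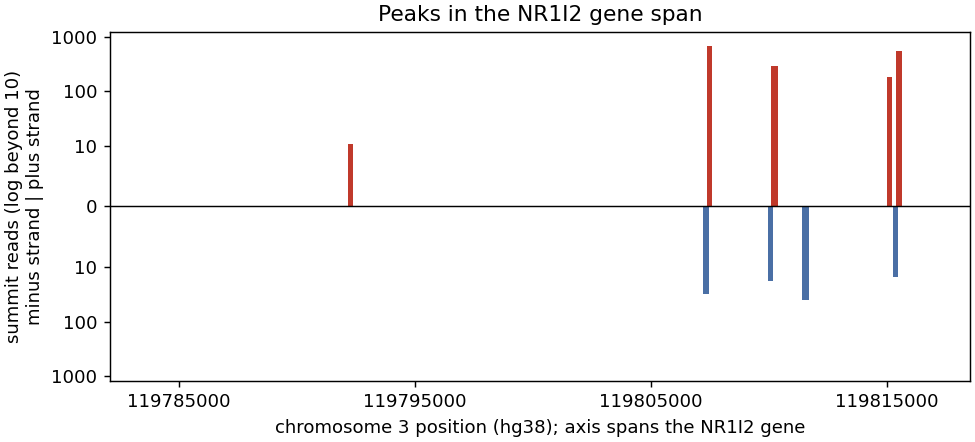
The x axis is the position on chromosome 3 over the NR1I2 gene span, each bar is a peak drawn to its width, and bar height is the recovered number of summit reads, plus strand upward in red and minus strand downward in blue, linear up to 10 and log beyond. The 5 plus-strand peaks reach 682 reads and the 4 minus-strand peaks reach 40 reads.

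The 10 peaks with the highest fold were mostly narrow and lay outside the genes with many peaks. The narrowest peak width, 200 bases, was taken as the length to which the caller extends a read. A peak of that width therefore holds reads that start at nearly 1 position. Peaks at most 2 bases wider, with over 200 reads, are called stacked, and the main set held 20. In the whole list 253 summits held more reads than 200 start positions, so reads with the same start were kept. Whether they are PCR copies was not tested. They lay in the spans of the coding genes SYCP2L and LOC124901446 on chromosome 6, DNM3 on chromosome 1, ZNF773 on chromosome 19 and ARHGAP39 on chromosome 8. The peaks at SYCP2L and LOC124901446 were on the plus strand and those at DNM3, ZNF773 and ARHGAP39 on the minus strand. Gene strand was not used here, so a peak need not come from RNA of the gene named. Others covered the noncoding gene LOC107985958 on chromosome 2, the mitochondrial RNR2-like pseudogene MTRNR2L1 on chromosome 17, and the pseudogene THEM7P with LOC107984322 on chromosome 11. The peak at THEM7P and LOC107984322 also overlapped the small noncoding RNA gene SNORA88, so its reads may come from that gene. The SYCP2L peak, at 10887604 to 10887803 on the plus strand, was 200 bases wide, with a fold of 49.8 and 12385 reads (Poisson interval 12168 to 12605) out of 12392 in its 10 kb. The DNM3 peak, at 171997383 to 171997582, was also 200 bases wide and held 4540 of 4541 reads. At ZNF773, at 57512864 to 57513064, all 1927 reads of the 10 kb lay under the summit. ARHGAP39 had 5396 reads at 144583246 to 144583445 and a fold of 48.7. The MTRNR2L1 peak, at 22524410 to 22524636, held 2453 reads at a fold of 48.2, and MTRNR2L1 has a near-identical counterpart in mitochondrial RNR2, between which aligned reads could be split. Of the other peaks, one on chromosome 15, at 45228535 to 45228734, had its centre in no gene and held 4828 reads. Another on chromosome 22, at 37675484 to 37675683, overlapped the start or end of LGALS1 but not with its centre, and held 1840 reads. Among all 34 peaks with a fold of 40 or more, 18 were at most 2 bases wider than 200 bases (52.9%, Wilson interval 36.7 to 68.5%), against 2 of the other 191 peaks with over 200 reads (1.05%, 0.288 to 3.74%).

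Peaks lay in genes, and mostly in coding genes. Of the 20919 main-set peaks, 20410 had their centre in a gene span (97.6%, Wilson interval 97.3 to 97.8%, jackknife SE over chromosomes 0.185 percentage points). Random positions gave 56.6%, a ratio of 1.72 (two-sided permutation p = 0.002, the smallest that 1000 placements can give). Coding genes held 92.0% of peaks against 43.6% at random, a ratio of 2.11. Pseudogenes held 2.87% against 1.47%, and small noncoding RNA genes 0.153% (32 peaks) against 0.0310%, a ratio of 4.93. With any overlap of 1 base in place of the centre, 132 peaks counted for small noncoding RNA genes (0.631%), against 0.0798% of random intervals of the same widths, a ratio of 7.91. Genes for lncRNA, counted where no coding or small RNA gene overlapped, held 2.53% against 11.4%, a ratio of 0.222. Positions in no gene made up 2.43% against 43.4%. Each of these shares differed from random placement (adjusted permutation p = 0.002). Random placement does not take into account which genes the cells express. Gene strand was not used here, so a peak counted for a gene may come from RNA of the other strand.

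CEMIP, a hyaluronan-binding protein gene on chromosome 15, held the most peaks, 40 on the plus strand, with a highest summit of 307 reads. GPHN, for the scaffold protein gephyrin, held 31 peaks over 1227209 bases, of which 7 lay on the opposite strand from the other 24, and only 15 of the 31 lay in no other gene. HUWE1, for a ubiquitin ligase, held 29 peaks, and DYNC1H1, for the dynein heavy chain, held 25. MYH9 (nonmuscle myosin), RNF213 and AGAP1 held 24 each, GMDS held 23 and the cadherin gene FAT1 held 22. These counts include peaks where genes overlap, and in no other gene lay 37 of the CEMIP peaks, 15 of RNF213, 20 of AGAP1 and 21 of GMDS. Per 10 kb of gene, DYNC1H1 had 2.72 peaks and CEMIP 2.32, against 0.253 for GPHN. In all, 10361 genes of any class held a peak centre. Among coding genes these were 8329 of 20037 (41.6%, Wilson interval 40.9 to 42.3%), with a median of 2 peaks, and 117 coding genes held 10 or more. Among lncRNA genes 1141 of 18322 held a peak (6.23%), among pseudogenes 855 of 17051 (5.01%) and among small noncoding RNA genes 32 of 3844 (0.832%). A gene without a peak may be unexpressed or too shallow, so its absence from the list is not read as a lack of binding.

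Small noncoding RNA genes had the highest median fold of any gene class, at 9.35 (bootstrap interval 7.01 to 14.9) over 32 peaks. RMRP, the RNA of the RNase MRP complex, reached a fold of 46.4, and RPPH1, the RNA of RNase P, reached 39.3. Pseudogene peaks had a median fold of 7.85 (7.58 to 8.14), peaks in no gene 6.92 (6.47 to 7.24), coding-gene peaks 5.92 (5.88 to 5.96) and lncRNA peaks 5.66 (5.56 to 6.04). The median in small noncoding RNA genes was 3.37 above that of all other peaks (permutation test, adjusted p = 1.2e-05). Pseudogene peaks were 1.91 above other peaks, and coding-gene peaks differed from them by -1.08 (permutation test, adjusted p = 1.2e-05 for each). For lncRNA peaks the difference was -0.320 (permutation test, adjusted p = 0.0058), and with only peaks at or above the median significance it was 1.43 (permutation p = 0.0001, the smallest that 10000 resamples can give). Peaks in any gene had a median fold of 5.97 against 6.92 in no gene, a difference of -0.953 (permutation p = 1e-05, the smallest that 100000 resamples can give). Median recovered reads were 21 in genes and 12 in no gene, and 22 in coding genes, 14 in pseudogenes and 48 in small noncoding RNA genes. With reads or −log10 q in place of fold, the differences for any gene, coding genes and no gene changed direction. With reads the pseudogene difference did so as well. The differences for small noncoding RNA genes kept their direction with both measures.

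Colon epithelial genes were in the list more often than length-matched random genes, and markers of liver, blood and connective tissue less often. Random lists were not matched on expression. For these lists and all those below, the comparison therefore cannot tell expression in the cells from binding by PXR. Of 30 goblet and colon epithelial markers 24 had a peak (80.0%, Wilson interval 62.7 to 90.5%), against 42.2% in random lists. They included the keratins KRT8, with a summit of 1147 reads and a fold of 17.7, and KRT18, with 721 reads, whose peak lies where the spans of both genes overlap. The adhesion gene EPCAM had 220 reads at a fold of 19.7, and PHGR1 had 190 reads at 25.9. None of 20 hepatocyte markers had a peak (0%, Wilson interval up to 16.1%), against 37.3% at random, and none of 20 blood and immune markers, against 34.2%. None of 390 olfactory receptor genes had one, against 25.1%. Of 18 fibroblast and endothelial markers 3 had a peak (16.7%, random 46.8%). These were COL1A2 with 10 reads and TAGLN with 21, on the minus strand, and ACTA2 with 6, on the plus strand. The TAGLN and ACTA2 peaks lay where 2 genes overlap. Gene strand was not used here, so none of these peaks need come from RNA of the marker. All of these lists except the epithelial one lay in the bottom 2.5% of random lists, but the fibroblast and endothelial list lay at the 4.71 percentile with only peaks at or above the median significance. Neuronal markers, with 4 of 18, lay at the 2.94 percentile and were not called. Their members SYT1 (141 reads at a fold of 37.2) and GRIN2A (23 reads) each had a peak in which all reads of the 10 kb lay under the summit, and TUBB3 had 18 reads and SLC32A1 had 4.

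Known target genes of PXR were not enriched in the list. Of 25 drug metabolism and transport genes, 8 had a peak (32.0%, Wilson interval 17.2 to 51.6%), against 46.8% in random lists, at the 6.99 percentile. TXNRD1, for thioredoxin reductase, had the deepest, with 183 reads at a fold of 25.1 on chromosome 12 from 104265277 to 104265830, where 3 genes of the table overlap. UGT1A1, UGT1A3 and UGT1A4, which code for glucuronosyltransferases and overlap, counted the same summit of 61 reads at a fold of 9.14, where 10 genes overlap, 469 bases from the upstream end of UGT1A1. No peak centre lay in CYP3A4 or ABCB1, the best known targets of PXR. Under the alternatives the list lay between the 1.52 percentile, with only peaks in 1 gene counted, and the 47.7 percentile, with only peaks at or above the median significance. Nuclear receptors and cofactors, in contrast, had a peak in 25 of 35 genes (71.4%, Wilson interval 54.9 to 83.7%, random 46.5%). Besides NR1I2 these included the corepressor NCOR1, with 11 peaks and a fold of 20.9 from 63 reads. PPARA had a peak of 21 reads at a fold of 15.5, on the minus strand, 201 bases wide and with all reads of its 10 kb under the summit, and another on the plus strand.

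Genes of glucose metabolism and lipid synthesis had peaks more often than random genes. Glucose metabolism had a peak in 19 of 23 genes (82.6%, random 43.1%), among them the glucose transporter SLC2A1 with 116 reads at a fold of 17.3, PKM with 10 peaks, LDHB with 7 and FBP1 with 1, which was 201 bases wide and held 21 of the 23 reads in its 10 kb. Lipid synthesis and cholesterol genes had one in 18 of 24 (Wilson interval 55.1 to 88.0%, random 46.0%). Of these SCD held 9 peaks, the sterol regulator SREBF2 held 12 and ME1 reached a fold of 11.5. Both lists lay in the top 2.5% of random lists. Fatty acid oxidation and PPARA targets, with 14 of 23 genes (60.9%, random 44.1%), did not, at the 94.2 percentile. Its members included ACAA1 at a fold of 11.2 and ACADM at 10.3. The ACADM peak was on the minus strand where 2 genes overlap, so it may come from RNA of the other gene.

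Genes for translation and RNA handling had peaks in most of their members. Expression was not matched for these lists either, so wide expression alone could give the same result. Of 88 cytosolic ribosomal protein genes 75 had a peak (85.2%, Wilson interval 76.3 to 91.2%, random 31.7%), led by RPLP1 with 526 reads at a fold of 32.3, RPS20 at 27.2, RPS2 at 27.1 and RPL35 at 24.2. Translation initiation and elongation factors, taken by gene symbol, had one in 55 of 71 (77.5%, random 42.5%). Highest were EEF1G at a fold of 27.3, EIF3F at 18.3, EIF5AL1 at 17.9 and EIF2AK1 at 17.7. EIF2AK1 codes for a kinase and not for such a factor, so the symbols also took in genes of other function. Splicing proteins of the hnRNP and SR families had one in 44 of 49 (89.8%, random 39.1%), with SRSF9 at a fold of 18.2, HNRNPD at 16.7, HNRNPA1L3 at 14.5 and HNRNPCL1 at 12.9. EIF5AL1, HNRNPA1L3 and HNRNPCL1 resemble other genes of their families closely, so their reads are uncertain. RNA decay and deadenylation genes had a peak in 30 of 32 (93.8%, random 47.4%), with EXOSC3, DCP1B, SMG1 and UPF1 highest at folds of 11.8 to 10.7. Genes for writers, erasers and readers of the RNA mark m6A had one in 15 of 19 (78.9%, random 46.8%), among them YTHDF3, YTHDF1, ALKBH5 and ZC3H13, and all of these lists lay in the top 2.5% of random lists. The m6A list lay at the 95.4 percentile with only peaks at or above the median significance.

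Genes of growth, stress and cell shape were also frequent. Heat shock and chaperone genes had a peak in 21 of 23 (91.3%, random 39.1%), led by the endoplasmic reticulum proteins PDIA4 at a fold of 19.9, PDIA3 at 17.9, CANX at 16.3 and HSP90B1 at 15.4. Cytoskeleton and junction genes had one in 24 of 27 (88.9%, random 43.3%), with ACTN4, MYH9, CTNNB1 and SPTAN1 highest. Proliferation genes had one in 23 of 26 (88.5%, random 41.7%), with MKI67 at a fold of 14.4, TYMS at 13.4, RRM2 at 12.7 and BIRC5 at 11.5. Immediate early genes had one in 17 of 21 (81.0%, random 32.4%), with IER5, DUSP1, FOSL2 and KLF10 at folds of 7.79 to 7.43. Replication dependent histone genes had one in 44 of 73 (60.3%, random 16.0%), with H4C3 at a fold of 29.1, H2AC20 at 28.0, H2AC17 at 26.6 and H2AC12 at 25.1. Histone genes are short and near-identical to each other, so which copy a read came from is uncertain. These lists all lay in the top 2.5% of random lists, as did 16 of the 23 lists tested.

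**Figure D3:**
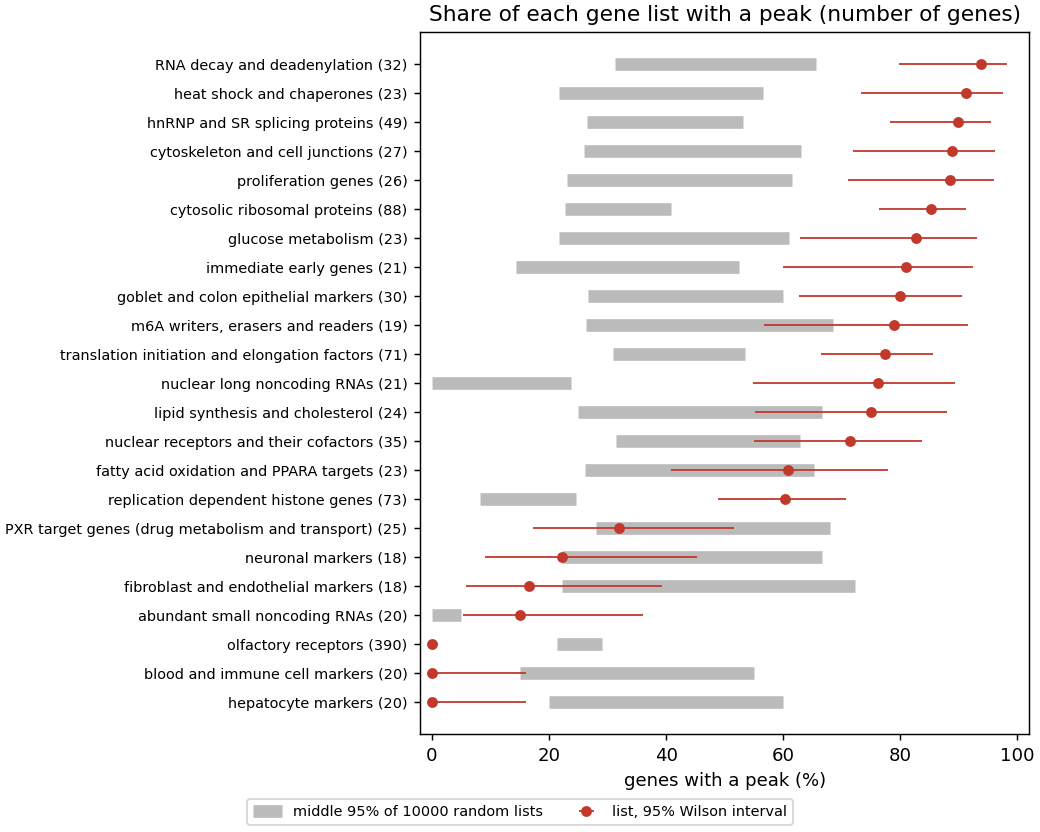
Each red point is the percentage of genes of a list with a peak, with its 95% Wilson interval, and each grey bar is the middle 95% of 10000 random lists matched on gene length and class; the number of genes stands in parentheses. The 16 lists above their grey bars run from abundant small noncoding RNAs (15.0%) to RNA decay and deadenylation (93.8%), and hepatocyte markers, blood and immune cell markers and olfactory receptors lie at 0%. Random lists were not matched on expression.

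Among noncoding RNAs, the list fixed under the name nuclear long noncoding RNAs had a peak in 16 of 21 genes (76.2%, Wilson interval 54.9 to 89.4%, random 8.87%). These were led by the snoRNA host genes SNHG8 with 121 reads at a fold of 24.1, SNHG1 with 546 reads at 23.4 and SNHG29 with 437 reads at 15.3, and by FTX with 8 peaks, whose highest fold of 10.9, from 13 reads, was in its only plus-strand peak, where 2 genes overlap. Where in the cell the RNAs of this list lie was not tested. With snoRNA host genes among its members, its share is not a result on nuclear RNAs as such. Of 20 abundant small noncoding RNAs 3 had a peak (15.0%, Wilson interval 5.24 to 36.0%, random 1.17%). RPPH1, on chromosome 14, held 37893 reads (Poisson interval 37512 to 38277) and RMRP, on chromosome 9, held 37566 (37187 to 37948), the deepest summits of the main set. TERC, the telomerase RNA, held 588 reads at a fold of 27.1. With random lists not matched on length, the small RNA list lay at the 95.1 percentile and was not called. Pseudogenes not counted, the 5 noncoding genes with the highest fold were LOC107985958 (48.9), LOC107984322 (48.2), LOC105373324 (47.6), LOC729732 (47.6) and DANCR (47.5). DANCR had 5090 reads in a peak that also overlapped the microRNA gene MIR4449. The LOC107984322 peak also overlapped SNORA88.

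Of the 37 mitochondrial genes 8 held a peak centre (21.6%, Wilson interval 11.4 to 37.2%), which was not compared with random lists. RNR2, the large ribosomal RNA, had 70362 reads at a fold of 16.1. The transfer RNA genes TRNG and TRNL2 had 2013 and 1066 reads on the plus strand. A peak centred in ND5 had 773 reads on the minus strand. Gene strand was not used here, so those reads need not come from ND5 RNA.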

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

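The tests on the fold ceiling and on NR1I2 in this part were chosen after the results were seen. Outside the main set, 14 peaks lay on the mitochondrial chromosome, and the highest of them, in RNR2, had 70362 reads at its summit. A further 98 peaks lay on 33 unplaced, unlocalized or alternate contigs. The highest summit of the whole list was among them, with 203980 reads at a fold just below 50, on an unlocalized contig of chromosome 22 from 135061 to 135310 on the plus strand. They stood out as signal in data that the main comparisons did not use, where a count of 0 would be the floor. Genes on such contigs were not assigned here.

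The fold in the list stops just below the ratio of 10 kb to 200 bases, which is 50. If the input library had set the background, a background could hold fewer reads in 10 kb than the summit above it, and 0 of 21031 peaks had such a background. The recovered background was a whole number of reads in 10 kb, or the common level of its strand, in 99.9% of peaks. These values argue against the input as the background and are consistent with a background taken from the 10 kb around each peak in the precipitated library. No biological explanation was tested. A fold of 5.55 at MALAT1, from 3528 reads, and of 49.8 at SYCP2L, from 12385 reads, then compare each summit with its surroundings and not with input RNA.

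NR1I2 had 4 peaks on the minus strand besides its plus-strand peaks, while no other of 1278 coding genes had over 2 on its minority strand, where only peaks in no other gene were counted and genes had 4 or more of them. Wrong-strand reads at every deeply covered position are argued against, since a peak on the other strand overlapped only 4 of 109 other peaks with 289 or more reads, isolated stacks left out (3.67%, Wilson interval 1.44 to 9.06%). One of these 4 was the 721-read peak shared by KRT8 and KRT18, with 19 reads on the other strand, so single positions are not covered by that share. Of the 4 minus-strand peaks in NR1I2 3 overlapped a plus-strand peak, against 19 of 65 minority-strand peaks in other genes with peaks on both strands (29.2%, exact Fisher p = 0.092, one-sided). Whether both strands of the transfected mouse sequence gave reads that aligned to the human gene therefore stays open, with 4 peaks too few to decide, as does antisense RNA of the human locus.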

How the results depend on the processing

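Alternatives on stacked peaks, gene-free stretches, recovered reads, strand and gene ends were chosen after seeing the data. Of 189 alternative values 173 were classed as unchanged. For tests this means the same direction and the same side of the threshold, and for plain counts and medians a value near the main one. The share of peaks in genes stayed at 1.61 to 1.72 times random under all 6 alternatives run. With only peaks at or above the median significance, the list held 10460 peaks and 6309 genes, by construction, since fewer peaks enter. The comparison of fold between features depended on the measure. With −log10 q in place of fold, peaks in any gene were higher than those in no gene by 1.08, coding-gene peaks differed from other peaks by 0.524 and peaks in no gene by -1.08. With recovered reads in place of fold the differences were 9 for any gene, 9 for coding genes, -7 for pseudogenes and -9 for no gene. With the significance threshold the lncRNA difference was 1.43. The fold divides by the local background, which is part of why measures differ, and beyond that the cause was not tested. The number of gene lists above random lists was 15 or 16 and the number below was 3 to 5 under the alternatives run. One by one, 88 of 92 list calls stayed, 3 were lost and 1 was gained. No paired analysis was possible because the list gives no values of single libraries. Alternatives on transcripts, exon priority, exon-only peaks, positions along transcripts and sequence motifs were not run, since exons and sequence were not used here. Depth limits single peaks, since a summit of 21 reads has a Poisson interval of 13.0 to 32.1.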

Other observations

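The tests in this part were chosen after the peak positions and strands were seen. Only for the doubled background was the value to judge it by fixed before its result. Peaks gathered at both ends of coding genes. Among 15841 peaks that lay in 1 coding gene of 5000 bases or more, 3787 lay within 1000 bases of the upstream end, taken on the strand of the peak (23.9%, Wilson interval 23.2 to 24.6%). Random positions in the same genes gave 3.63% (two-sided permutation p = 0.002, the smallest possible). Within 1000 bases of the downstream end lay 2077 peaks (13.1%, random 3.63%, permutation p = 0.002). With each gene span divided into 20 equal parts, the first held 25.0% of peaks and the last 17.9%. Peaks at the upstream end had a median fold of 7.68, against 5.65 at the downstream end and 5.48 elsewhere, while median reads were 20, 22 and 22. The highest-fold peaks of NCOR1, SCD, SLC2A1, EPCAM, RPLP1 and ACTN4 had their centres 163 to 231 bases from the upstream end, and those of LDHB, PHGR1 and EEF1G 84 to 129 bases from the downstream end. These genes were picked from the named ones after their positions were seen.

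One technical explanation for the gathering at gene ends is that the 10 kb window of the background reaches beyond the gene and so holds few reads. The background was therefore doubled for peaks within 5000 bases of a gene end. The ratio to random placement was then 7.13 at the upstream and 3.54 at the downstream end, against 6.59 and 3.62 without doubling. The doubling was the same for peaks further inside the gene, whose windows reach beyond it less. That can raise the ratio at the ends, so the test cannot decide how much the window contributes. A higher density of mature RNA at the ends of gene spans, which are exonic, may contribute and was not tested, since exons were not used here. Where the protein binds, as opposed to where RNA was recovered, also stays open.

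Within a coding gene, peaks kept to 1 strand. In 1278 genes with 4 or more peaks in no other gene, 99.1% of 7284 peaks lay on the majority strand of their gene, against 66.1% when strands were drawn at random (permutation p = 0.002). All peaks shared a strand in 1215 of these genes, and TNK2, BORCS5 and KIAA1217, with 2 minority peaks each, came next after NR1I2. MALAT1, NEAT1 and GAPDH were chosen after their values were seen. MALAT1, a nuclear RNA, had 8 peaks with summits of 780 to 3528 reads and folds of 1.53 to 5.55. NEAT1, the RNA of paraspeckles, had 9 peaks with folds of 2.38 to 6.01, and GAPDH had a summit of 1137 reads at a fold of 14.3.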
